A study of Homo sapiens with 14 samples.

How the data were processed

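Per the submitters' processing notes, reads were aligned with STAR 2.4.1d to hg19 and counted by gene with featureCounts 1.4.4 of Subread, and the counts were analysed with limma 3.22.1. The deposited count table held whole numbers for 57373 Ensembl genes, and these counts were the input of every test. The authors' score table of 33330 genes, rounded to whole numbers, divided the counts of each library by 1 factor and by no gene length. Over 441 genes with a score of at least 200 the authors' factors were 0.802 to 1.153, close to the TMM factors found here (0.792 to 1.165), and the scores were not used further. Names came from a table of symbols for 51498 identifiers and from GENCODE 29 for 333 more, and 5542 identifiers, with 0.80% of counts, kept no name. GENCODE 29 is built on another genome release than hg19, so no positions are given.

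Tests used edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM and filtered by expression, which kept 16785 genes, and 1 quasi-likelihood model with a mean per group was fitted to all 14 libraries (7 residual degrees of freedom, biological coefficient of variation 6.48%). The 13 comparisons were tested by the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg within each comparison, with genes called at an adjusted p under 0.05. SE was the absolute log2 fold change over the square root of F. Interactions were the TNF effect with HF minus that without HF. Alternatives used DESeq2 1.42.0, limma-voom of limma 3.58.1, other scalings, filters and thresholds, and a lane term. Others were fits to the compared groups alone and refits without each library. The groups, the 13 comparisons, their tests and alternatives, the 19 fixed genes and the 27 gene lists were set before the data were examined. Scaling by library size alone and the tests of explanations were added after values had been seen. The differences between 24 h and 8 h in the HF effect (HF before TNF against TNF alone) and in the interaction were outside that plan, and were defined after the counts had arrived but before any test was run.

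Gene lists covered the amino acid response, amino acid synthesis with one-carbon metabolism, amino acid transporters, tRNA synthetases, the unfolded protein response and NF-kB feedback. They covered chemokines, cytokines and growth factors, adhesion and antigen presentation, matrix proteases, prostaglandin and steroid genes, interferon-stimulated genes, and collagen and matrix. Also covered were myofibroblast and TGF-β genes, cell cycle, p53 targets, cholesterol synthesis, NRF2 targets, autophagy and lysosome, ribosomal proteins and mitochondrially encoded genes. The last were histones listed as lacking poly-A tails, and markers of fibroblasts, macrophages, lymphocytes, endothelial and mural cells, and chondrocytes and adipocytes. The lists held 498 genes, of which 20 matched no named gene in the count table. Among these were CCL3, CCL4, CCL5, MMP12, MRC1, TRAC, PECAM1 and all 13 mitochondrial genes, so that the mitochondrial list had 0 tested genes. As 5542 identifiers kept no name, some of the 20 may have been counted under an unnamed identifier. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry were the alternatives. Where a list was given with 2 p-values, the second was from the estimated correlation.

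Genes were named by a rule: the 19 fixed genes, the 5 highest and 5 lowest changes of a comparison among called genes with non-overlapping libraries and at least 5 CPM in the higher group, and up to 3 higher and 3 lower genes of each list by p. Not every gene the rule reached is printed. Genes outside it are said to have been chosen after their values were seen. Where a group had 0 counts, a bound was set by a floor of 3 counts over the group ("at least"), and with 1 to 3 counts a ratio with its 95% interval is given. Such intervals and floors cover counting error only. Levels are CPM over library sizes scaled by TMM, and the figure of levels adds 0.1.

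Replicates differed by more than sampling noise in every group, with chi-square per degree of freedom from 2.69 (HF at 24 h) to 19.53 (TNF at 8 h). The model shared 1 spread per gene over all groups. Fits to the compared groups alone moved counts both ways. Calls fell from 9614 to 7896 (TNF at 8 h against untreated) and from 4830 to 3695 (interaction at 8 h). They rose from 5965 to 7725 (TNF in HF-treated cells at 24 h) and from 2420 to 3441 (HF at 24 h against 8 h). No label says whether the 2 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical. Both untreated libraries and the first of every other group were sequenced in 1 lane (8 libraries) and the other 6 in a second lane. Mean TMM factors ran from 0.794 (TNF at 8 h) and 0.917 (TNF at 24 h) through 0.96, 1.034, 1.088 and 1.091 to 1.163 (HF at 24 h), so scaling mattered most for TNF at 8 h.

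In a test of the method, counts were simulated with the mean of every gene taken from untreated cells (15661 genes in the fit). True changes were planted in the simulated libraries of HF at 8 h. The edgeR test recovered 66.2% of 68 genes changed 1.5-fold, 89.4% of 66 changed 2-fold and 100% of 66 changed 4-fold, and called 17 of 15441 unchanged genes (0.11%). Its list test gave a shifted list of 20 genes an adjusted p = 1.58e-37 and called 0 of 20 unchanged lists. Few of the simulated genes were changed, and all were drawn independently. The test thus did not cover scaling under widespread change, or lists of genes that vary together.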

Results

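To ask how HF, described by its depositors as an inhibitor of aminoacyl tRNA synthetases, alters the inflammatory response of synovial fibroblasts, poly-A RNA was compared across 14 libraries of primary human fibroblast-like synoviocytes from rheumatoid arthritis. Cells were left untreated, or were given 300 nM HF or vehicle for 16 h and then 10 ng/ml TNF or vehicle for 8 h or 24 h, which gave 7 groups of 2 libraries (n = 2). The libraries held 24466481 to 32922534 assigned reads and detected 21584 to 23067 genes. The 10 most abundant genes took 8.5% to 11.7% of the reads of a library. Interferon-stimulated genes took 0.14% to 0.21% of reads in libraries without TNF, 3% to 3.21% in those with TNF, and 0.99% to 1.62% in those with both. Untreated cells carried no time in their labels and served as the only baseline at both times. Times count from the start of the TNF or vehicle period, and no label says whether HF stayed on after its 16 h. Below, levels are CPM scaled by TMM (mean ± SD, n = 2), effects are log2 fold changes ± standard error (SE), and p-values are adjusted within each comparison.

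The first principal component took 49.9% of the variance. It set TNF-treated cells (scores of 94.5 to 98.5) against HF-treated cells (−79.8 to −77.9), with cells given both between them (−20.7 to 2.8). Untreated cells lay in that middle range as well (−19.9 and −17.5). Along the second component (26.0%), untreated cells lay at 94.9 and 100.4 and cells given both at −61.1 to −56. The 2 libraries of a group lay side by side, with correlations of log2 CPM of 0.9918 to 0.9979.

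**Figure D1:**
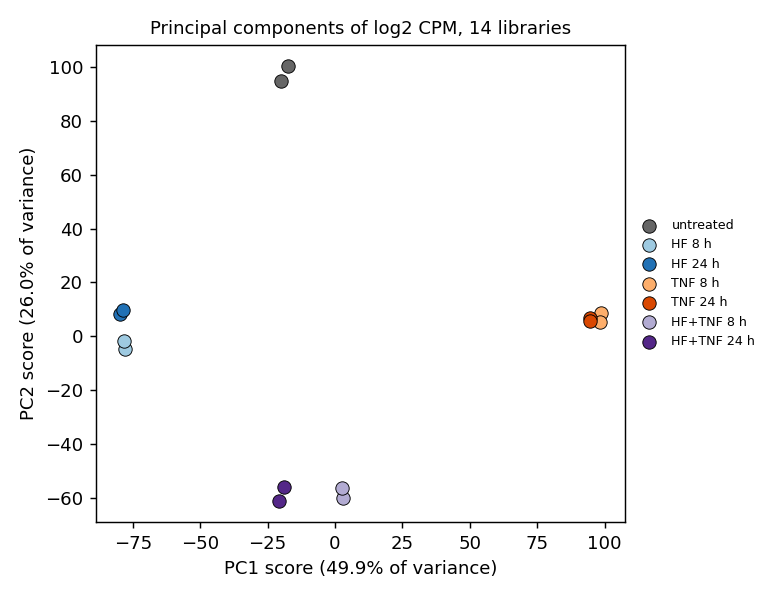
Scores of the 14 libraries on the first (49.9% of variance, horizontal) and second (26.0%, vertical) principal components of log2 CPM. Each point is 1 library coloured by group, and the groups separated by HF and by TNF more than by time.

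HF alone raised genes of the amino acid response and lowered the chemokine CXCL12 at 8 h. The pseudokinase gene TRIB3 rose from 36.5 ± 2.13 to 488 ± 24.3 CPM (log2 fold change 3.74 ± 0.08, adjusted p = 6.44e-19). DDIT3 rose from 21.4 ± 0.861 to 157 ± 2.95 CPM, and asparagine synthetase ASNS from 70.2 ± 3.9 to 230 ± 6.17 (1.71 ± 0.07, adjusted p = 4.38e-15). CXCL12, which draws leukocytes into the joint, fell from 836 ± 24 to 55.6 ± 4.36 CPM (−3.91 ± 0.08). IL6 rose from 6.11 ± 1.06 to 54.3 ± 4.13 (3.14 ± 0.10). The 19 genes fixed in advance included the collagen gene COL1A1, which did not change (10080 ± 1430 against 9933 ± 784 CPM, −0.02 ± 0.10, adjusted p = 0.873). In all, 4782 genes rose and 5061 fell of 16785 tested, and with scaling by library size alone 5357 and 4567.

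Among lists of genes fixed in advance, the amino acid response held the clearest rise with HF at 8 h. Of 22 tested genes 20 rose and 1 fell (median 1.68, adjusted p = 6.37e-30, or 0.00591 with an estimated correlation). Among them were VEGFA (92.8 ± 2.03 to 458 ± 10.1 CPM), SESN2 (44.2 ± 2.03 to 160.3 ± 12) and CHAC1 (10.6 ± 0.712 to 30.3 ± 1.94). ATF4 itself fell from 432 to 345 CPM. Synthesis of serine, glycine, proline and asparagine with one-carbon metabolism had 11 genes higher and 2 lower of 16 (median 0.80, adjusted p = 1.12e-05, 0.0393 with an estimated correlation). There GOT1 rose from 25.5 ± 1.04 to 190 ± 17.8 and MTHFD2 from 98.2 to 272 CPM. PHGDH fell from 253 ± 15.3 to 135 ± 1.16 and SHMT1 from 16 to 2.72. Amino acid transporters (8 higher, 1 lower of 13, median 0.91) gave an adjusted p = 1.06e-08 (0.00591 with an estimated correlation). SLC7A11 (48.3 ± 5.58 to 320 ± 0.292 CPM), SLC38A1 (1.63) and SLC7A1 (1.62) rose most surely, and SLC43A1 (−0.95) fell. The enzymes that charge tRNAs rose as a list, 19 of 20 (median 0.87, adjusted p = 4.18e-11, 0.0176 with an estimated correlation). WARS1 went from 187 ± 13.2 to 880 ± 1.54 CPM, IARS1 from 265 to 732, and GARS1 from 344 to 937. The glutamyl-prolyl enzyme EPRS1 went from 229 ± 23.3 to 445 ± 12.8 CPM (0.96 ± 0.07), and QARS1 alone fell (−1.25).

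The chaperone response of the endoplasmic reticulum was split with HF at 8 h, with 8 genes higher and 3 lower of 17 (median 0.12, adjusted p = 0.0171, but adjusted p = 0.13 with an estimated correlation). HSPA5 rose 7.05-fold to 3328 ± 22.2 CPM and HYOU1 from 52.5 to 181. CALR fell from 704 ± 7.55 to 339 ± 19.8 and PDIA4 from 145 to 86. Of 26 collagen and matrix genes 6 rose and 18 fell (median −0.54, adjusted p = 0.000203, but adjusted p = 0.13 with an estimated correlation). The small proteoglycans LUM (1877 ± 106 to 464 ± 25.2 CPM) and DCN (5436 ± 43.7 to 1995 ± 69.2) fell with SPARC (2543 ± 35.3 to 872 ± 37.3). PLOD2 (1.04), which modifies collagen lysines, and POSTN (0.94) rose. Fibroblast markers had 3 higher and 8 lower of 13 (median −0.81, adjusted p = 0.0108, but adjusted p = 0.13 with an estimated correlation). PDPN went down from 36.9 to 6.09 and PDGFRA from 607 to 138 CPM, and UAP1 went up from 123 to 690. TGF-β and myofibroblast genes moved both ways (6 higher, 11 lower of 18, median −0.42, adjusted p = 0.98). TGFB2 rose from 24.8 ± 1.95 to 218 ± 16.3 CPM as CCN2 fell from 1729 to 631.

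Chemokines, cytokines, NF-kB feedback genes and proteases did not pass as lists with HF at 8 h. Chemokines had 5 higher and 5 lower of 17 (adjusted p = 0.635), where the median was 0.37 but the mean −0.22 and the direction of the test was lower. CXCL2 rose from 0.458 to 7.53 and CXCL3 from 0.206 to 2.67 CPM, and CX3CL1 (−2.36) fell. Cytokines and growth factors had 4 higher and 9 lower of 17 (median −0.32, although the test pointed up, adjusted p = 0.995). TSLP went up from 3.77 to 35.3 and IL7 down from 11.4 to 1.55 CPM. NF-kB feedback genes had 7 higher and 8 lower of 21 (median −0.09, adjusted p = 0.358). SOD2 fell from 1060 ± 39.1 to 174 ± 27.8 and NFKBIA from 45.2 ± 0.579 to 19.7 ± 1.82, and TNFAIP3 rose from 40.1 to 55.2 CPM. Of 15 matrix proteases and inhibitors 3 rose and 7 fell (median −0.64, test upward, adjusted p = 0.98). The aggrecanase gene ADAMTS5 rose 8.94-fold to 1317 ± 23.5 CPM and MMP2 fell from 7777 ± 756 to 3199 ± 55.8. Interferon-stimulated genes had 5 higher and 20 lower of 36 (median −0.57, adjusted p = 0.0108, but adjusted p = 0.635 with an estimated correlation). GBP2 went down from 39.6 ± 1.66 to 2.22 ± 0.999 CPM. Adhesion and antigen presentation genes (1 higher, 14 lower of 19, median −0.47, adjusted p = 0.0486, but adjusted p = 0.418 with an estimated correlation) included VCAM1 (165 ± 11.5 to 115 ± 6.84 CPM) and ICAM1 (35.7 to 28.8). Prostaglandin and steroid genes (1 higher, 7 lower of 8, median −1.68) gave an adjusted p = 0.000495, but adjusted p = 0.13 with an estimated correlation. PTGS2 went up from 2.04 to 12.3 and PTGER2 down from 58.4 to 9.4 CPM. Cholesterol synthesis genes (2 higher, 12 lower of 18, median −0.65) gave an adjusted p = 0.0028, but adjusted p = 0.13 with an estimated correlation. INSIG1 fell from 72.4 to 25.9 CPM.

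Among the largest rises with HF at 8 h was that of the IL-33 receptor gene IL1RL1 (1.08 ± 0.118 to 154 ± 3.16 CPM, 7.13 ± 0.12), followed by BEX2 (5.64 ± 0.34) and ARFGEF3 (5.56 ± 0.22). The unnamed gene ENSG00000264868 (ratio 281 lower, 95% interval 77.5 to 2330), ANGPTL7 (20 ± 2.45 to 0.121 ± 0.0841 CPM, −7.37 ± 0.30), INSC (−6.10) and INMT (−6.07) were among the deepest falls. CCL2 rose from 54.9 ± 7.1 to 85.1 ± 8.92 CPM and CCL20 by a ratio of 9.75 (95% interval 1.42 to 420, adjusted p = 0.0204). CXCL8 (adjusted p = 0.18), MMP1 (0.461) and CXCL10 (0.842) stayed low in both groups. Adjusted over the list alone, all these counts were the same except for amino acid synthesis (11 higher, 3 lower) and cholesterol synthesis (2 higher, 13 lower). The 2 libraries of each group did not overlap for 76.7% of tested genes, against 33.3% by chance.

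With HF at 24 h the same stress genes were high, and loss of matrix and sterol transcripts now passed the stricter list test. TRIB3 stood at 462 ± 15.2 CPM (3.66), ASNS at 231 ± 4.49 (1.72), DDIT3 at 119 ± 6.39 (2.47), SESN2 at 138 (1.64), CHAC1 at 29.7 (1.49) and EPRS1 at 462 ± 2.01 (1.01). LUM fell to 253 ± 15.7 CPM (−2.89), DCN to 1221 ± 56.9 (−2.15), CXCL12 to 35.7 ± 3.36 (−4.55), and COL1A1 to 7305 ± 28.8 (−0.46 ± 0.10, adjusted p = 0.000353). Of 16785 genes 4420 rose and 4759 fell against untreated cells. Scaling by library size alone, which moved the median of all genes to 0.155, made that 5975 higher and 3715 lower.

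By list, the amino acid response had 19 higher and 2 lower genes at 24 h (median 1.55, adjusted p = 2.38e-31, 0.00499 with an estimated correlation), amino acid synthesis 11 and 2 (0.76, 5.49e-07, 0.0149), transporters 10 and 1 (0.80, 1.91e-08, 0.00499) and tRNA synthetases 17 and 2 (0.84, 2.04e-12, 0.0138). The serine enzyme PSAT1 rose from 193 to 511, SLC7A5 from 90.3 to 396 and WARS1 to 810 CPM, and AARS1 fell slightly (−0.27). Collagen and matrix genes had 3 higher and 20 lower (median −0.69, adjusted p = 1.31e-12, 0.0149 with an estimated correlation), fibroblast markers 3 and 9 (−1.13, 3.6e-06, 0.0163) and cholesterol synthesis 0 and 13 (−0.84, 4.53e-06, 0.024). SPARC fell to 642 ± 23.5 and INSIG1 to 19 CPM, and PDGFRA changed by −2.05. Several other lists lost their call with an estimated correlation. Prostaglandin and steroid genes had 1 higher and 6 lower (median −1.69, adjusted p = 4.21e-05, but adjusted p = 0.0512 with an estimated correlation), adhesion and antigen presentation 1 and 15 (−0.44, 0.00226, but adjusted p = 0.144), and interferon-stimulated genes 1 and 20 (−0.60, 0.00225, but adjusted p = 0.442). Myofibroblast genes had 5 higher and 11 lower (−0.78, 0.00635, but adjusted p = 0.27 with an estimated correlation), NF-kB feedback 2 and 11 (−0.39, 0.0176, but adjusted p = 0.0766) and the unfolded protein response 9 and 4 (0.22, 0.0246, but adjusted p = 0.126). Within them HSD11B1 (−3.56), CD44 (1230 to 527 CPM), VCAM1 (to 75.8 ± 5.75), GBP2 (−3.42), TAGLN (−1.51), SOD2 (−2.32) and CALR (to 307 ± 7.55) fell. HSPA5 (to 2440 ± 34) and TGFB2 (to 201) rose. Chemokines (3 higher, 5 lower, median −0.79, adjusted p = 0.33), cytokines (4 and 9, −0.96, 0.469) and proteases (4 and 8, −0.60, 0.653) did not pass as lists. Even so, IL6 (31.3 ± 0.264 CPM, 2.35), CXCL2 (3.80) and ADAMTS5 (1845 ± 12.9, 3.65) rose. CXCL8 fell to 0.526 CPM (−0.86, adjusted p = 0.0414), ICAM1 by −0.38 and NFKBIA by −0.99, and CCL2 (adjusted p = 0.705), MMP1 (0.382), CXCL10 (0.925) and CCL20 (0.344) did not change. LAMP3, a lysosomal membrane gene of activated cells, had one of the largest rises (ratio 376, 95% interval 67.2 to 14900, at 7.06 CPM), as did IL1RL1 (65.3 ± 0.111 CPM, 5.90). INSC (ratio 221 lower, 75.1 to 1070) and LRRTM2 (144 lower, 48.8 to 700) were among the deepest falls. Adjusted over the list alone, 1 more gene was lower in prostaglandin and steroid genes (7), adhesion (16), myofibroblast genes (12) and cholesterol synthesis (14).

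**Figure D2:**
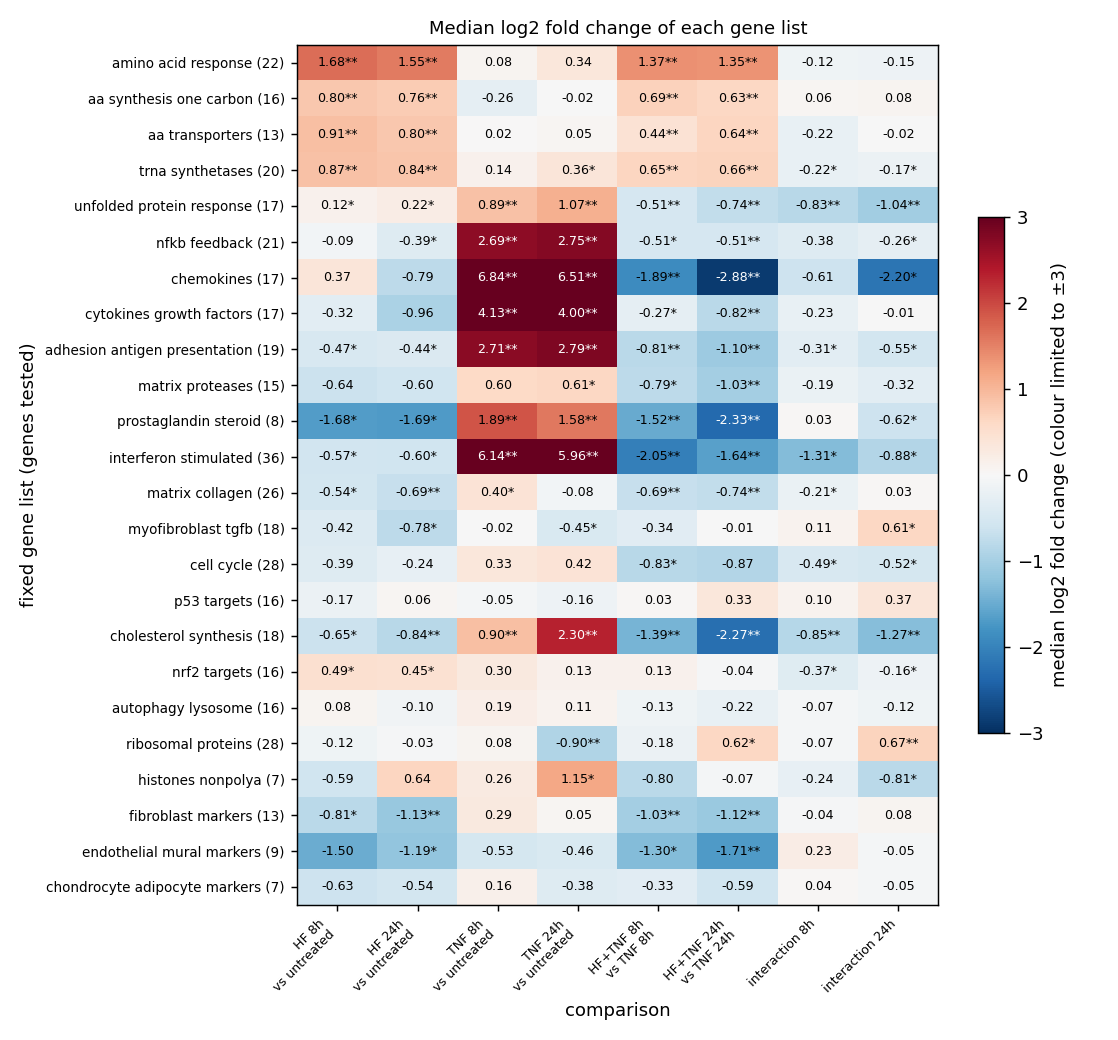
Median log2 fold change of the tested genes (colour, limited to ±3) of 24 fixed gene lists (down) in 8 comparisons (across), n = 2 libraries per group. A star marks an adjusted p under 0.05 with the preset correlation and a double star one that also held with an estimated correlation, as for the rise of interferon-stimulated genes with TNF (median 6.14 at 8 h) and their lower levels when HF was given before TNF (−2.05).

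TNF alone induced chemokines, interferon-stimulated genes, adhesion molecules and a collagenase. At 8 h CXCL8 rose from 0.951 ± 0.156 to 1269 ± 130 CPM (10.37 ± 0.15) and CCL2 from 54.9 ± 7.1 to 2251 ± 107 (5.36). The adhesion molecule VCAM1 rose from 165 ± 11.5 to 7884 ± 658 (5.58 ± 0.09), ICAM1 from 35.7 ± 0.703 to 1853 ± 225 (5.70), and the cytokine IL6 from 6.11 ± 1.06 to 128 ± 2.18 (4.38). MMP1 rose from 0.242 ± 0.0586 to 95.9 ± 2.6 CPM at 8 h (8.59 ± 0.18) and to 219 ± 20.6 at 24 h (9.78). TRIB3 (to 24.4 ± 1.04 CPM, −0.58 at 8 h) and ASNS (71 CPM, adjusted p = 0.847) were not induced at 8 h, and both were slightly higher at 24 h (0.26, adjusted p = 0.0086, and 0.30). At 8 h 4909 genes rose and 4705 fell, and at 24 h 4786 and 4334.

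Every one of 36 interferon-stimulated genes rose at both times (median 6.14 at 8 h, adjusted p = 1.97e-161, 0.000296 with an estimated correlation, and 5.96 at 24 h, 2.35e-160, 0.000327). RSAD2 rose from 0.224 to 1395 ± 124 CPM (12.57), GBP4 from 0.309 to 1053 ± 72.6 (11.75), IFIT3 from 35.2 ± 2.63 to 3220 ± 184 (6.51), and at 24 h IFI27 from 2.98 to 469 ± 19.8 (7.30). All 21 NF-kB feedback genes rose as well (median 2.69, 1.16e-49, 4.21e-05 with an estimated correlation at 8 h, and 2.75, 2.87e-46, 7.42e-05 at 24 h). Examples were TNFAIP2 (99.4 to 5506 ± 562 CPM), TNFAIP3 (40.1 ± 3.1 to 1761 ± 19.9) and NFKBIA (45.2 to 498 ± 5.06). Chemokines had 16 higher and 1 lower of 17 at either time (median 6.84, 6.94e-47, 0.000652 with an estimated correlation, and 6.51, 8.09e-46, 0.000385). CXCL10 reached 326 ± 43.3 CPM at 8 h (ratio 8760, 95% interval 2420 to 72300) and 220 ± 11.8 at 24 h (5860, 1620 to 48400). CCL20 reached 11.5 ± 0.801 CPM (614, 110 to 24300) and then 28.7 ± 0.431 (1530, 273 to 60300). CXCL12 was the 1 that fell, to 449 ± 8.25 CPM (−0.90) and then 186 ± 1.93 (−2.17). Cytokines had 15 higher and 1 lower at 8 h (median 4.13, 1.14e-30, 0.000257 with an estimated correlation) and 16 and 1 at 24 h (4.0, or 3.70 with bounds for genes at 0 counts, 9.46e-29, 0.000133). The B-cell factor TNFSF13B stood at 686 ± 88.7 CPM (7.81), TNFSF10 at 311 ± 25.5 (6.66), IL32 at 379 (5.90, 24 h), and IL11 went down (−1.67 at 8 h). All 19 adhesion and antigen presentation genes rose (median 2.71, 6.94e-47, 0.00041 with an estimated correlation, and 2.79, 5.31e-51, 0.000327). The peptide transporter TAP1 went from 20.3 to 354 CPM at 8 h.

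Sterol and secretory genes also rose with TNF, the first mostly late. Cholesterol synthesis had 16 of 18 genes higher at 8 h (median 0.90, adjusted p = 1.06e-06, 0.0198 with an estimated correlation) and 18 of 18 at 24 h (2.30, 5.87e-27, 0.000385). HMGCS1 went from 21.8 ± 2.5 to 126 ± 17 and then 283 ± 10.7 CPM and SQLE from 43.4 to 269 at 24 h. The unfolded protein response had 17 of 17 higher at 8 h (0.89, 2.25e-06, 0.0116) and 14 at 24 h (1.07, 1.11e-08, 0.00379). Its chaperone HSPA5 went from 472 ± 36.9 to 1079 ± 40 and 1372 ± 19.1 CPM. Prostaglandin and steroid genes had 6 higher and 2 lower at both times (1.89, 1.67e-06, 0.0331, and 1.58, 1.05e-05, 0.0389). HSD11B1, which reactivates cortisol, went up from 5.71 to 128 ± 1.98 and 380 ± 22.5 CPM and PTGS2 from 2.04 to 30 at 8 h, and PTGIS (−0.85) fell. Proteases had 10 higher and 4 lower at 8 h (0.60, adjusted p = 0.165) and 11 and 4 at 24 h (0.61, 0.0428, but adjusted p = 0.276 with an estimated correlation). MMP3 was at least 38.3-fold higher at 8 h (2.12 ± 0.586 CPM) and at least 47.5-fold at 24 h (2.67 ± 0.427). PLAUR rose from 26.1 to 80.5 and TIMP3 fell from 2190 to 1222 and 630 CPM. Collagen and matrix genes had 18 higher and 2 lower at 8 h (0.40, 0.00303, but adjusted p = 0.268 with an estimated correlation) and 7 and 10 at 24 h (median −0.08 but mean 0.06, adjusted p = 0.819). PLOD2 went from 197 to 1145 and COL3A1 from 1462 ± 118 to 3040 ± 110 CPM at 8 h. COL1A1 rose to 13710 ± 2490 at 8 h (0.44 ± 0.10, adjusted p = 0.000528) and was back at 9741 ± 453 at 24 h (−0.05, adjusted p = 0.694). With library-size scaling the median of all genes at 8 h moved from −0.027 to −0.408. The sizes of the COL1A1 rise and of the collagen median at 8 h thus depended on scaling. ELN fell from 302 to 67.4 at 24 h.

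Ribosomal protein genes fell at 24 h of TNF, 27 of 28 (median −0.90, adjusted p = 1.85e-14, 0.0337 with an estimated correlation). Histones listed as lacking poly-A tails rose there (6 higher, 0 lower of 7, 1.15, 0.0223, but adjusted p = 0.278 with an estimated correlation). They may move with RNA quality, but whether the RNA counted lacked tails was not tested. RPL3 fell from 1646 ± 167 to 597 ± 16.2 CPM, RPLP0 from 1746 ± 81.7 to 648 ± 5.03 and RPL4 from 1603 ± 6.82 to 677 ± 6.41. At 8 h 3 of them were called higher (0 when adjusted over the list alone), with a median of 0.08 that turned to −0.30 under library-size scaling (adjusted p = 0.942). The tRNA synthetases had 10 higher and 4 lower at 8 h, when their median of 0.14 turned to −0.24 under library-size scaling (adjusted p = 0.063). At 24 h they had 14 and 2 (0.36, 0.0164, but adjusted p = 0.276 with an estimated correlation). WARS1, an interferon target, rose from 187 to 2547 ± 14.1 CPM, and EPRS1 did not change (adjusted p = 0.821 and 0.0722). Amino acid response genes did not pass as a list (9 higher, 8 lower at 8 h, adjusted p = 0.668, and 14 and 4 at 24 h, median 0.34, 0.0946). Neither did amino acid synthesis (3 and 9, median −0.26, 0.156, and 5 and 5, −0.02, 0.717) or transporters (6 and 3, 0.942, and 5 and 3, 0.981). ATF3 rose from 6.39 to 98.9 CPM at 8 h and DDIT3 did not (adjusted p = 0.739). Myofibroblast genes had 6 higher and 4 lower at 8 h (median −0.02, mean 0.13, 0.769) and 4 and 12 at 24 h (−0.45, 0.0273, but adjusted p = 0.426 with an estimated correlation). The growth factor CCN2 fell from 1729 to 430.2 CPM. Fibroblast markers moved both ways (7 higher, 3 lower, 0.209, and 5 and 6, 0.767). PDPN rose from 36.9 to 333 ± 5.54 CPM at 8 h and PDGFRB fell from 928 to 304.

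Genes without counts before TNF included GBP5, at least 669-fold at 8 h (37.5 ± 2.99 CPM) and 1100-fold at 24 h, and IBSP at least 393-fold and 398-fold. MX2 rose by ratios of 3910 (95% interval 1080 to 32300) and 5530 (1530 to 45700). SLC40A1 (25.1 to 0.449 CPM, −5.76) and BMF (−5.90) were among the deepest falls at 8 h and SLC14A1 (302 to 4.7, −6.00) and ADH1B (−5.16) at 24 h. Adjusted over the list alone, counts differed only for collagen (19 higher at 8 h, 11 lower at 24 h), tRNA synthetases (5 lower at 8 h, 15 higher at 24 h) and ribosomal genes at 8 h among the lists above. With upper-quartile scaling, which moved the median of all genes to −0.225 at 8 h and −0.145 at 24 h, the splits became 3562 higher and 6564 lower at 8 h and 3801 and 5700 at 24 h. Library-size scaling moved that median to −0.408 and −0.179 and gave 2698 and 8532 at 8 h and 3600 and 6039 at 24 h. A mean of at least 1 CPM gave 3880 and 4735, then 3881 and 4290. Relative to that median the collagen list was at 0.43 at 8 h under every scaling. A scaling factor shifts the list and that median alike, so this tested nothing about scaling.

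In cells given HF before TNF, MMP1 was nearly absent and interferon-stimulated genes and CXCL10 were lower than with TNF alone. Changes are from TNF alone to HF before TNF at the same time. MMP1 fell from 95.9 ± 2.6 to 0.591 ± 0.00331 CPM at 8 h (−7.33 ± 0.16, 161-fold) and from 219 ± 20.6 to 0.783 ± 0.0686 at 24 h (−8.12 ± 0.14, 278-fold). CXCL10 fell from 326 ± 43.3 to 20.9 ± 3.99 CPM at 8 h (−3.97 ± 0.12) and from 220 ± 11.8 to 2.72 ± 0.494 at 24 h (−6.34 ± 0.15). VCAM1 (7884 against 8782 ± 602 CPM at 8 h, adjusted p = 0.0823, and 2762 against 2488 ± 67.5 at 24 h, 0.0907) did not pass the threshold. IL6 was higher at both times (128 ± 2.18 to 211 ± 9.53, 0.72 ± 0.08, and 132 ± 2.56 to 204 ± 3.11, 0.64). TRIB3 rose from 24.4 ± 1.04 to 552 ± 16.7 CPM at 8 h (4.50 ± 0.08, adjusted p = 1.19e-19) and from 43.6 ± 3.4 to 562 ± 22.6 at 24 h (3.69).

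Interferon-stimulated genes had 35 of 36 lower with HF at 8 h (median −2.05, adjusted p = 7.61e-45, 0.00957 with an estimated correlation) and 35 at 24 h (−1.64, 3.21e-28, 0.0148). The antiviral gene RSAD2 went down from 1395 to 148 ± 11.5 and IFIT3 from 3220 to 596 ± 84.5 CPM at 8 h and IFIT2 from 2191 to 251 at 24 h. Chemokines had 4 higher and 10 lower at 8 h (−1.89, 7.91e-08, 0.0348) and 2 and 15 at 24 h (−2.88, 3.1e-17, 0.00726). CXCL9 (120 to 4.98 CPM) and CXCL11 (56.7 to 1.93) fell with CXCL10 at 8 h. The neutrophil chemokine CXCL8 rose from 1269 ± 130 to 2522 ± 395 CPM at 8 h (0.99 ± 0.09, adjusted p = 2.85e-09) and fell from 1152 ± 44.7 to 541 ± 14.7 at 24 h (−1.09 ± 0.09, 5.27e-10). CCL20 rose from 11.5 ± 0.801 to 31.2 ± 4 and fell from 28.7 ± 0.431 to 8.9 ± 0.0584, and CXCL2 rose at both times (1.02 and 0.86). CCL2 did not change at 8 h (adjusted p = 0.708) and fell from 1920 to 1282 ± 46.3 CPM at 24 h (−0.58). Cytokines had 8 higher and 9 lower at 8 h (−0.27, 0.0217, but adjusted p = 0.0646 with an estimated correlation) and 7 and 9 at 24 h (−0.82, 0.0015, 0.0183). IL1A went up from 3.65 to 29.6 and IL1B from 10.3 to 26.5 CPM at 8 h, and the antagonist IL1RN went down from 22.8 to 0.302 and TNFSF10 from 311 to 24.5.

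NF-kB feedback genes had smaller median falls than interferon-stimulated genes, a difference not tested here. The NF-kB list had 4 higher and 11 lower of 21 at 8 h (−0.51, 0.0223, but adjusted p = 0.0646 with an estimated correlation). At 24 h it had 0 and 14 (−0.51, 3.2e-05, 0.0102). NFKBIA fell from 498 to 273 ± 5.19 and from 460 to 192 ± 1.09 CPM and TRAF1 from 192 to 69.3 at 8 h. RELB (0.65) and BIRC3 (0.44) rose at 8 h, and TNFAIP3 did not change (adjusted p = 0.392) until 24 h (−0.17, 0.0287). Adhesion and antigen presentation genes had 1 higher and 17 lower at 8 h (−0.81, 2.23e-06, 0.0433) and 0 and 17 at 24 h (−1.10, 3.49e-10, 0.0148). HLA-E fell from 225 to 95 and NLRC5 from 200 to 63.7 CPM at 8 h, and CD40 from 41.2 to 6.28 at 24 h. ICAM1 rose at 8 h (0.27, adjusted p = 0.00356) but fell at 24 h (−0.84). Every prostaglandin and steroid gene, 8 of 8, fell at both times (−1.52, 1.37e-09, 0.0145, and −2.33, 1.82e-11, 0.00726). The phospholipase PLA2G4A went from 156 to 10.3 at 8 h and HSD11B1 from 380 to 22.6 CPM at 24 h. All 18 cholesterol synthesis genes fell as well (−1.39, 3.74e-16, 0.00644, and −2.27, 1.47e-27, 0.000425), such as HMGCS1 from 283 ± 10.7 to 33.8 ± 2.84 CPM at 24 h. Proteases had 3 higher and 11 lower at 8 h (−0.79, 0.0465, but adjusted p = 0.182 with an estimated correlation) and 3 and 12 at 24 h (−1.03, 0.0018, 0.0427). At 8 h MMP2 went down from 8041 to 3842, PLAUR by −1.42, and ADAMTS5 up from 218 to 1464 CPM.

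Collagen and matrix genes had 0 higher and 23 lower of 26 at 8 h (−0.69, 2.16e-10, 0.0201) and 2 and 23 at 24 h (−0.74, 3.42e-11, 0.0115). LUM fell from 4423 ± 468 to 718 ± 14.7 and from 4784 ± 175 to 368 ± 54.2 CPM, and COL3A1 from 3040 to 837 ± 14.3 at 8 h. COL1A1 fell from 13710 to 10880 ± 664 at 8 h (−0.33, adjusted p = 0.00591) and from 9741 to 6723 ± 293 at 24 h (−0.53). Library-size scaling moved the median of all genes at 8 h from −0.041 to 0.232, so the size of that 8 h fall depended on scaling. Fibroblast markers had 3 higher and 9 lower at 8 h (−1.03, 0.000566, 0.0433) and 2 and 10 at 24 h (−1.12, 4.23e-05, 0.0172). PDPN went down from 378 to 18.3 CPM at 24 h and PDGFRA from 341 to 43.1 at 8 h. The unfolded protein response had 2 higher and 12 lower at 8 h (−0.51, 0.000274, 0.0342) and 3 and 12 at 24 h (−0.74, 0.000195, 0.0214). At 8 h CALR fell from 1121 to 322 and PDIA4 from 264 to 81, but HSPA5 rose, from 1079 to 1614 ± 22.5 CPM. Myofibroblast genes did not pass at 8 h (4 higher, 9 lower, median −0.34, mean 0.00, test upward, adjusted p = 0.68) or 24 h (6 and 5, median −0.01, mean 0.14, 0.195). TGFB2 went up from 68.1 to 546 CPM and THBS1 down (−0.98) at 8 h.

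Amino acid lists also rose with HF before TNF. The amino acid response had 19 higher and 3 lower at 8 h (1.37, 1.76e-27, 0.00644 with an estimated correlation) and 19 and 0 at 24 h (1.35, 4.64e-21, 0.00726). ASNS went up from 71 ± 2.93 to 230 ± 1.79 CPM at 8 h (1.69) and from 86.5 ± 0.839 to 285 ± 4.75 at 24 h (1.72), and SESN2 from 36.4 to 187 and DDIT3 from 21.9 to 127 at 8 h. Amino acid synthesis (12 higher, 3 lower, 0.69, 3.44e-07, 0.0145, then 14 and 1, 0.63, 5.29e-08, 0.00857) included GOT1, up from 23 to 186 CPM at 8 h. Transporters (8 and 1, 0.44, 3.44e-07, 0.00644, then 9 and 1, 0.64, 5.14e-07, 0.00726) included SLC7A5, up from 108 to 460 at 24 h. Among tRNA synthetases (13 and 5, 0.65, 1.34e-05, 0.0488, then 13 and 4, 0.66, 7.6e-06, 0.0373) EPRS1 rose from 233 to 388 at 8 h, but WARS1 fell from 2547 to 1867 ± 66.9 CPM. Ribosomal protein genes had 16 lower and none higher at 8 h, where their median of −0.18 turned to 0.09 under library-size scaling (adjusted p = 0.23). At 24 h they had 26 higher and 1 lower (0.62, 2.36e-09, but adjusted p = 0.0523 with an estimated correlation), and RPLP0 rose from 648 ± 5.03 to 1582 ± 50.3 CPM. This comparison used the same 2 libraries of TNF at 24 h as the ribosomal fall with TNF alone, so the results were not independent. With HF alone at 24 h the ribosomal median was −0.03.

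In the same comparison large rises were those of BEX2 (at least 95-fold at 8 h, 5.95 CPM), IL1RL1 (1.56 to 108 ± 0.203 CPM at 8 h) and the Notch target HES1 (0.0794 to 15 CPM at 24 h, 7.48 ± 0.32). IBSP fell at least 387-fold at 8 h and by a ratio of 702 (95% interval 194 to 5800) at 24 h, IL33 from 16.4 to 0.174 CPM at 8 h, and RCSD1 at least 122-fold at 24 h. At 8 h 4215 genes rose and 5255 fell with HF, and at 24 h 4327 and 5361. Library-size scaling moved the median of all genes to 0.232 and 0.211, making the splits 6631 and 3582 at 8 h and 6597 and 3947 at 24 h, and upper-quartile scaling gave 4937 and 4685 at 8 h. Adjusted over the list alone, counts differed by 1 gene for interferon-stimulated genes at 8 h (36 lower), adhesion at 8 h (2 higher), the amino acid response at 24 h (1 lower) and ribosomal genes at 8 h (17 lower).

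**Figure D3:**
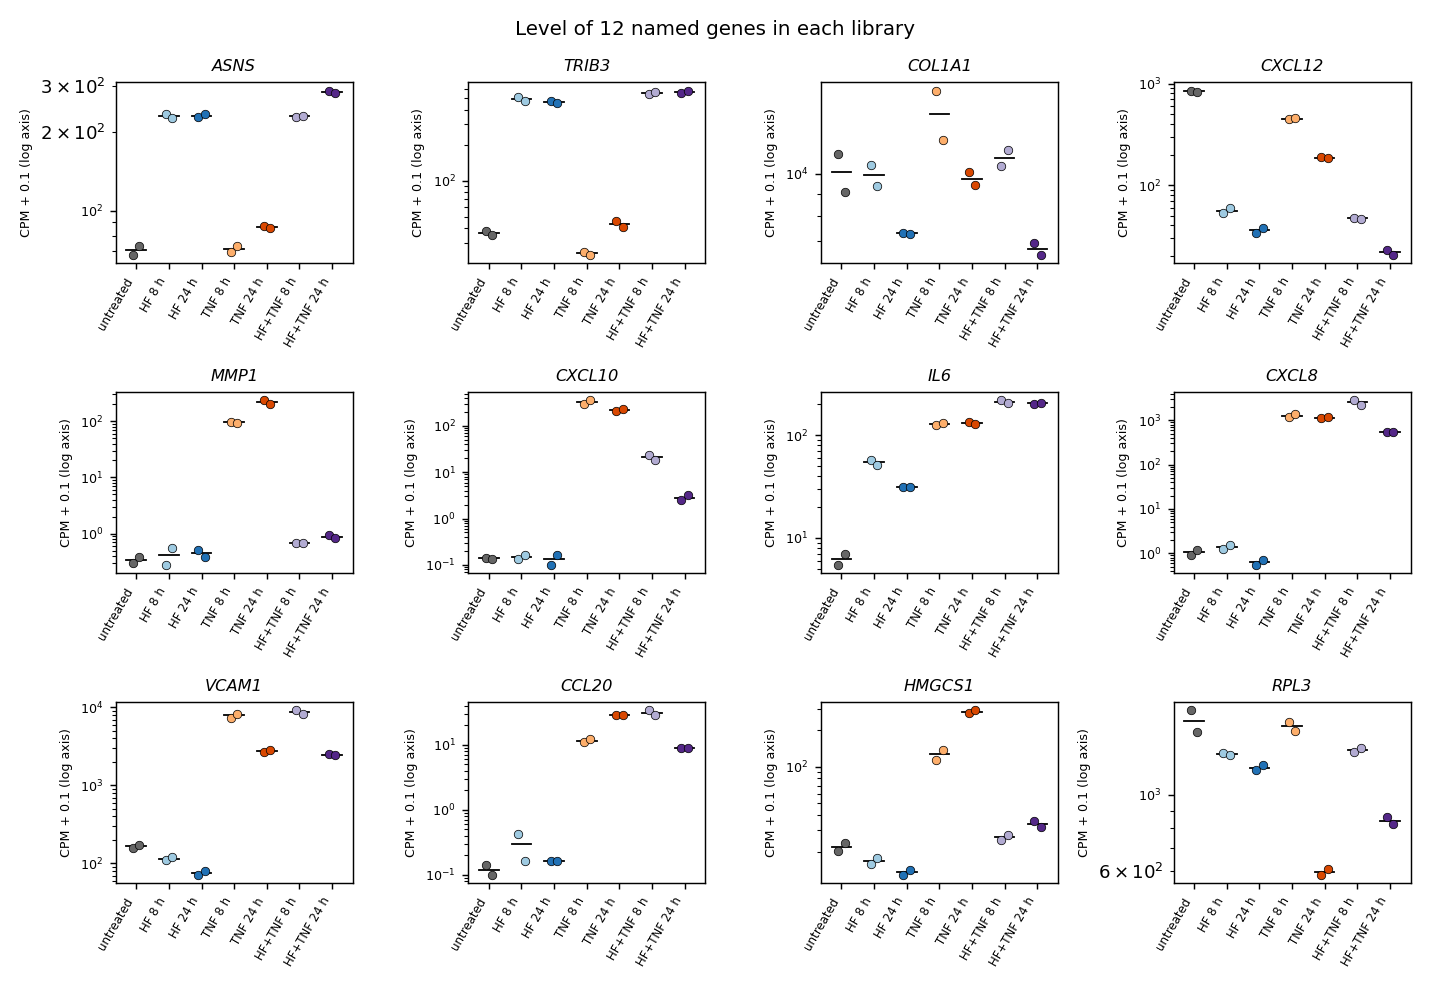
Levels of 12 genes in the 14 libraries by group, as CPM plus 0.1 on a log axis. Points are libraries and lines are group means (n = 2), with MMP1 at 95.9 CPM in TNF-treated cells and 0.591 CPM after HF and TNF at 8 h, while VCAM1 stayed near 7884 and 8782 CPM.

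HF-treated cells still responded to TNF. In cells given HF, all 36 interferon-stimulated genes rose at 8 h (median 5.26, adjusted p = 4.27e-197, 0.000134 with an estimated correlation) and 24 h (5.39, 3.05e-226, 8.5e-05), as did 21 of 21 NF-kB feedback genes (2.68, 1.79e-84, and 2.4, 6.36e-73) and 19 of 19 adhesion genes (2.33, 4.86e-69, and 2.38, 5.27e-70). Chemokines had 16 higher and 1 lower at 8 h (5.15, or 4.69 with bounds, 1.2e-60) and 13 and 1 at 24 h (4.48, 6.71e-40), and cytokines 14 and 1 (3.24, or 3.03 with bounds, 3.75e-42) and 14 and 0 (2.71, or 2.70 with bounds, 5.58e-39). Prostaglandin and steroid genes had 6 higher and 2 lower at 8 h (1.47, 5.12e-05, but adjusted p = 0.0634 with an estimated correlation) and 5 and 3 at 24 h (0.59, 0.0525). Cholesterol synthesis moved both ways at 8 h (5 higher, 4 lower, 0.06, adjusted p = 0.449) and higher at 24 h (16 and 0, 0.90, 1.68e-09, 0.00937), and the unfolded protein response did not pass (2 and 5, 0.434, then 5 and 3, 0.942). When adjusted over the list alone, 15 chemokines rose at 24 h, 6 cholesterol genes were higher at 8 h and 4 unfolded protein response genes lower at 24 h.

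Counted over the genome, TNF raised 2857 genes and lowered 3348 in HF-treated cells at 8 h, and raised 2861 and lowered 3104 at 24 h. With library-size scaling, which moved the median of all genes to −0.237 at 8 h and −0.124 at 24 h, these were 1975 and 5998, and 2210 and 4178. Upper-quartile scaling gave 2290 and 4036 at 24 h with that median at −0.112. The balance tipped the other way with no filter (3444 higher and 2547 lower at 8 h, 3653 and 2294 at 24 h), DESeq2 (2945 and 2666, then 2910 and 2565), RLE factors (3113 and 2981, then 3144 and 2847) and a mean of at least 1 CPM (2958 and 2816, then 2970 and 2771). Genes raised by TNF both with and without HF numbered 2313 at 8 h (836 by chance) and 2256 at 24 h (816 by chance), and those lowered in both 2251 (938) and 2207 (801), while 305 of 4869 and 291 of 4754 went opposite ways. Across genes the TNF effects with and without HF correlated at 0.72 and 0.71.

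**Figure D4:**
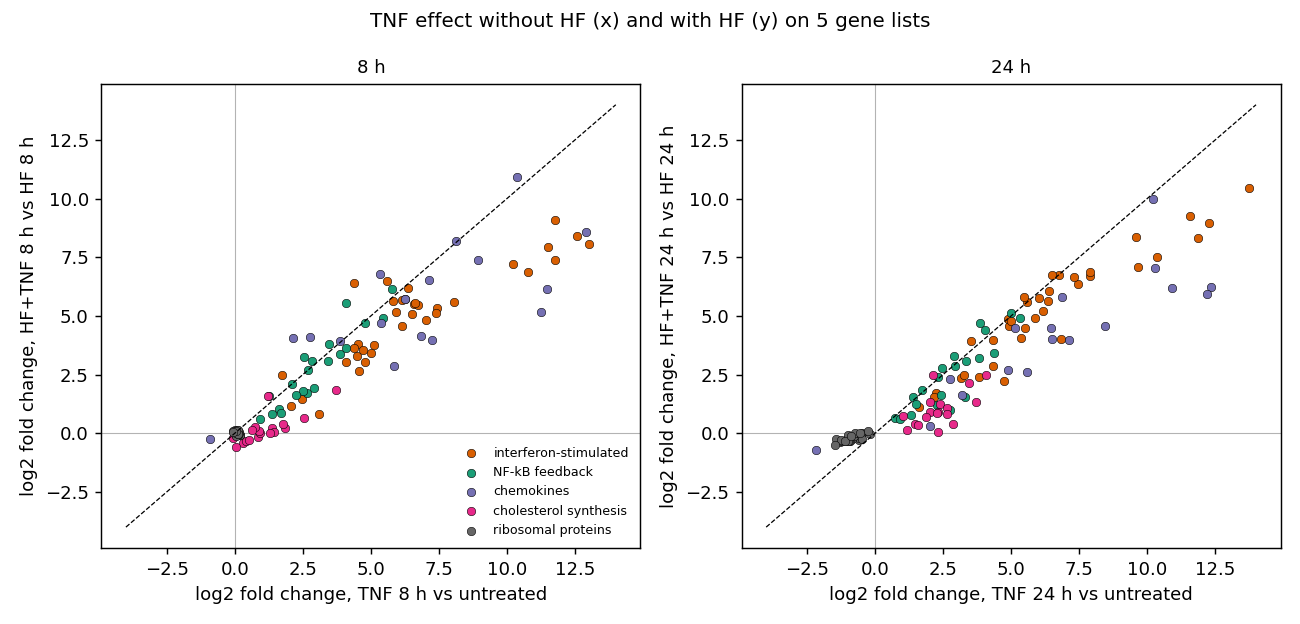
Effect of TNF without HF (horizontal, log2 fold change) against its effect in HF-treated cells (vertical) for the genes of 5 fixed lists at 8 h and 24 h. Each point is 1 gene and the dashed line marks equal effects, below which most cholesterol synthesis genes lay (median 2.30 without and 0.90 with HF at 24 h).

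Whether HF changed the size of the TNF effect was tested as an interaction. There were 1908 genes higher and 2922 lower at 8 h, and 1640 and 2407 at 24 h. The TNF effect without HF was taken against untreated cells, which had no time label, so time in culture may enter these values. MMP1 had one of the lowest values (−7.77 ± 0.62 at 8 h, adjusted p = 5.95e-09, and −8.63 ± 0.61 at 24 h), and IL6, whose level was highest with both agents, also had a smaller TNF fold in HF-treated cells (−2.42 ± 0.13 and −1.71 ± 0.13). The TNF fold of VCAM1 was larger in HF-treated cells (0.68 ± 0.11 and 0.97 ± 0.11). For VCAM1, HF alone had lowered the level, and the level with TNF did not differ with HF past the threshold. The TNF fold was smaller for CCL2 (−0.67 and −0.63), and for ICAM1 larger at 8 h (0.58) and smaller at 24 h (−0.46). For CXCL8 (adjusted p = 0.209 and 0.714), CCL20 (0.33 and 0.0931), ASNS (0.923 and 1) and COL1A1 (0.0957 and 0.769) no difference was shown. CCL20 had 1 count in untreated cells and 11 and 4 with HF alone at 8 h and 24 h, so its test had little power. CXCL10, nearly absent without TNF, did not pass at 8 h (−4.34, 0.0546) and passed at 24 h (−6.13, 0.0421).

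The unfolded protein response had a uniform interaction, 16 of 17 genes lower at both times (median −0.83, adjusted p = 8.95e-22, 0.0011 with an estimated correlation, and −1.04, 7.38e-22, 0.000909). HSPA5 was lower by −2.24 ± 0.09 and −1.82 ± 0.09 and HYOU1 by −1.83 and −1.38. Cholesterol synthesis had 1 higher and 15 lower at 8 h (−0.85, 1.89e-12, 0.00874) and 0 and 15 at 24 h (−1.27, 1.13e-23, 0.000909), with HMGCS1 at −1.90 ± 0.15 and −2.37 ± 0.15. Interferon-stimulated genes had 2 higher and 29 lower at 8 h (−1.31, 2.75e-19, but adjusted p = 0.12 with an estimated correlation) and 0 and 23 at 24 h (−0.88, 4.21e-10, but adjusted p = 0.184). IRF1 lay at −1.74 and −1.43 and IFIT2 at −2.25 and −2.80. Ribosomal genes did not differ at 8 h (adjusted p = 0.798) and had 26 higher at 24 h (0.67, 7.38e-22, 0.0324), RPLP0 by 1.17 ± 0.08. Other lists lost their call with an estimated correlation. The tRNA synthetases had 1 higher and 8 lower at 8 h (−0.22, 0.000462, but adjusted p = 0.189) and 2 and 5 at 24 h (−0.17, 0.0113, but adjusted p = 0.266), with WARS1 at −2.68 and −2.50. Adhesion genes had 2 and 10 at 8 h (−0.31, 0.0306, but adjusted p = 0.454 with an estimated correlation) and 1 and 13 at 24 h (−0.55, 0.000206, but adjusted p = 0.173), with CD274 at −3.23 and −3.11. NF-kB feedback at 24 h (2 and 9, −0.26, 0.0262, but adjusted p = 0.173) held SOD2 (0.87), and chemokines at 24 h (1 and 9, −2.20, 0.0118, but adjusted p = 0.287) held CXCL2 (−2.94). Collagen at 8 h had 1 higher and 10 lower (−0.21, 0.000817, but adjusted p = 0.268 with an estimated correlation). At 24 h myofibroblast genes had 10 and 2 (0.61, 3.7e-09, but adjusted p = 0.082), with CCN2 at 2.29 and THBS1 at 1.28, and prostaglandin genes 0 and 5 (−0.62, 0.00347, but adjusted p = 0.177), with PTGS2 at −2.81. Cell cycle genes had 0 and 8 at 8 h (−0.49, 0.0402, but adjusted p = 0.678 with an estimated correlation) and 1 and 10 at 24 h (−0.52, 0.0276, but adjusted p = 0.563). NRF2 targets had 0 and 9 (−0.37, 0.000638, but adjusted p = 0.158) and 2 and 5 (−0.16, 0.0113, but adjusted p = 0.198), and histones 0 and 4 at 24 h (−0.81, 0.0307, but adjusted p = 0.316). Adjusted over the list alone, lower genes at 8 h were 17 in the unfolded protein response, 30 interferon-stimulated (3 higher) and 9 tRNA synthetases. At 24 h counts higher and lower were then 1 and 16 for cholesterol synthesis, 1 and 24 for interferon-stimulated genes, 2 and 6 for tRNA synthetases and 3 and 9 for NF-kB feedback. They were 1 and 11 for chemokines, 1 and 5 for prostaglandin genes, 11 and 3 for myofibroblast genes, 1 and 12 for the cell cycle and 27 and 0 for ribosomal genes. RET (−6.19) and TNFSF18 (−5.65) were among the lowest at 8 h, and HES1 (5.61), EGR2 (4.53) and KIT (4.43) among the highest at 24 h. With upper-quartile scaling, which moved the median of all genes to 0.107, the split at 8 h was 2835 higher and 2010 lower. With library-size scaling, which moved it to 0.173, it was 3472 and 1658 at 8 h and 2170 and 1980 at 24 h. No filter gave 2421 and 2244 at 8 h and 2159 and 1951 at 24 h, and a mean of at least 1 CPM gave 2657 and 2139, then 2146 and 2005.

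To follow TNF-induced genes as a set, those raised at least 2-fold at one time were read at the other, so that the TNF libraries used to choose them were not used to read them. Of 1934 genes raised at 24 h, 1172 (60.6%) were lower with HF at 8 h and 216 (11.2%) higher (median −0.83), against 27.5% and 26.9% of the 14851 others (median 0.02). Of 1920 raised at 8 h, 1335 (69.5%) were lower with HF at 24 h and 174 (9.1%) higher (median −1.02), against 27.1% and 27.9% of 14865 others. HF effects with and without TNF overlapped as well: 2966 genes rose in both at 8 h (1201 by chance) and 3449 fell in both (1584), and at 24 h 2983 (1139) and 3377 (1520). Opposite directions were found for 567 of 6982 genes called in both at 8 h and 487 of 6847 at 24 h.

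Between 8 h and 24 h the HF-treated cells changed least. There 994 genes rose and 1426 fell, but without the first library of HF at 8 h only 1182 were called, and without the first or second of HF at 24 h 1219 or 1097. Collagen and matrix genes fell (0 higher, 19 lower, median −0.33, adjusted p = 3.62e-16, 0.0298 with an estimated correlation) with myofibroblast genes (1 and 10, −0.37, 2.31e-13, 0.0305) and fibroblast markers (1 and 7, −0.35, 9.75e-07, 0.0298). Histones listed as lacking poly-A tails rose (5 and 0, 0.54, 1.02e-08, 0.0298). With TNF alone 3423 rose and 3571 fell, all 28 ribosomal genes among the latter (−0.95, 6.61e-44, 0.00573). There 17 of 18 cholesterol synthesis genes rose (1.14, 7.48e-26, 0.00174). Collagen (1 and 19, −0.38, 8.58e-07, but adjusted p = 0.131 with an estimated correlation), myofibroblast genes (2 and 13, −0.49, 2.77e-07, but adjusted p = 0.131) and histones (5 and 0, 0.99, 0.000259, but adjusted p = 0.138) lost their call. With both agents 2640 rose and 2969 fell, chemokines (0 and 14, −1.11, 2.65e-17, 0.0156), NF-kB feedback (2 and 15, −0.51, 1.08e-09, 0.00794) and collagen (1 and 23, −0.58, 1.75e-13, 0.0189) falling and 7 of 7 histones rising (1.42, 7.63e-10, 0.0233). When adjusted over the list alone, counts with HF were 2 and 11 for myofibroblast genes, 1 and 8 for fibroblast markers and 6 and 0 for histones. With TNF they were then 17 and 1 for cholesterol synthesis and 6 and 0 for histones, and with both agents 15 chemokines fell. Library-size scaling turned these splits to 2010 and 863 with HF, 5905 and 2006 with TNF (median of all genes 0.222) and 5092 and 1784 with both (0.176), and upper-quartile scaling gave 1456 and 1095 with HF, 4013 and 3036 with TNF and 2971 and 2724 with both. A mean of at least 1 CPM gave 1299 and 1285 with HF and 3423 and 3231 with TNF, where no filter gave 3410 and 3338.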

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

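The length and GC test of ribosomal genes and scaling by library size alone were chosen only after results had been seen, and the other tests were written down before they were run. The fall of ribosomal protein genes at 24 h of TNF (median −0.90 over 28 genes) was set against technical sources. Genes matched for transcript length, GC content and level numbered 153 (median length 768.25 against 771, GC 51.7% against 51.2%, level 739.4 against 503.1 CPM). They had a median of 0.15 (95% interval 0.04 to 0.31), with 45 lower and 74 higher, which argued against a bias by length or base content. That interval resampled genes and held the libraries fixed. Across scalings, with and without the median of all genes taken off, the ribosomal median stayed between −0.89 and −1.07. A scaling factor shifts these genes and that median alike, so it cannot make a fall relative to the median gene. RLE, upper-quartile and library-size scaling moved the median of all genes from −0.006 to −0.013, −0.145 and −0.179. All were downward, so none could have lessened the fall before that median was taken off. The summed level of 86 ribosomal genes with 1502 pseudogenes changed by −0.80 (log2), from 39910 and 40630 to 22920 and 23290 CPM with a pseudogene share of 0.788% and 0.802%, arguing against reads moved to pseudogenes. Histones listed as lacking poly-A tails rose in the same comparison (6 higher, 0 lower of 7, median 1.15, adjusted p = 0.0223). With an estimated correlation the adjusted p was 0.278. Whether the histone RNA counted lacked tails was not tested. From 8 h to 24 h with both agents the histone median was 1.42 while that of ribosomal genes was −0.15. RNA quality, which no label gives, was not excluded. A regulated loss of ribosomal transcripts after long TNF exposure was another candidate explanation that was not tested. The same libraries of TNF at 24 h entered the ribosomal changes with HF before TNF at 24 h and from 8 h to 24 h of TNF. They also entered the interaction at 24 h and the differences between the times. Those results were thus not independent of the fall with TNF, and RNA quality was not excluded for them either.

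With HF before TNF, CXCL8 was higher than with TNF alone at 8 h and lower at 24 h. In 14 refits without each library the effect lay between 0.82 and 1.15 at 8 h and between −1.13 and −1.04 at 24 h, never closer to 0 than 0.82, which argued against a single library as the source. Each of these groups had 1 library in either lane, so the fit with a lane term (0.99 at 8 h and −1.09 at 24 h) tested nothing. Under 3 other scalings it was never closer to 0 than 0.84 (at least 1.0 at 8 h and at most −0.84 at 24 h), arguing against scaling.

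Interferon-stimulated genes fell more with HF than NF-kB feedback genes, by −1.53 at 8 h (medians −2.05 and −0.51) and −1.13 at 24 h (−1.64 and −0.51). TNF had also induced them more (6.14 against 2.69 at 8 h and 5.96 against 2.75 at 24 h), and larger induction alone may account for a larger fall. Adjusted for induction through 4852 and 4729 other TNF-raised genes, the difference was −0.38 (95% interval −0.90 to −0.03) at 8 h and 0.79 (0.02 to 1.22) at 24 h, of opposite sign, and only 15 and 13 of 36 interferon-stimulated genes lay within the range of induction of the NF-kB genes. The intervals resampled genes as if independent and held the libraries fixed, so they do not cover the spread between libraries. The HF effect and the induction at each time also shared the TNF libraries. The explanation was thus left undecided. A scaling factor shifts both lists alike and cancels in their difference, so the values under other scalings (−1.13 to −1.53) tested nothing.

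The effect of HF before TNF, against TNF alone, differed between 24 h and 8 h for 3599 genes, 328 of them called in opposite directions at the 2 times. These included CCL20 (24 h minus 8 h, −3.13), CXCL8 (−2.08) and ICAM1 (−1.11). By list the difference had medians of −1.18 for chemokines, −0.61 for cholesterol synthesis (adjusted p = 0.0227 each with an estimated correlation), −0.32 for NF-kB feedback (0.0309) and 0.74 for ribosomal proteins (0.0188). The interaction of HF and TNF differed between the times for 2456 genes.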

How the results depend on the processing

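Of the settings here, only scaling by library size alone was chosen after results had been seen. Each group had 2 libraries, so no split or outlier test was possible, and fits without 1 library left an arm with a lone library assumed to vary like the other groups. No paired analysis was possible because no label ties libraries of different groups by culture or donor. Lane split every treated group and not the untreated, and the lane term was the only blocked fit. Untreated cells had no time label, so comparisons with them were not matched for time, unlike those between treated groups at 8 h or 24 h. No label says that untreated cells received vehicle, so these comparisons and the interactions may also carry an effect of vehicle.

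Asking for a 2-fold change left calls of 3602 (HF at 8 h against untreated), 3082 (HF at 24 h), 3877 (TNF at 8 h), 3571 (TNF at 24 h), 3555 and 3710 (HF before TNF against TNF alone at 8 h and 24 h), 1855 and 1763 (TNF in HF-treated cells), 1264 and 1273 (interactions), and 221, 1567 and 1107 (24 h against 8 h with HF, TNF and both), as the higher threshold requires. Without 1 library, calls for HF at 24 h against 8 h were 1182 and 1697 (first and second library of HF at 8 h), 1219 and 1097 (first and second at 24 h). The cause was not tested.

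The share of TNF-induced genes lowered by HF moved from 60.6% at 8 h to 56.2% without a filter, 67.5% with a mean of at least 1 CPM, 54.5% with library-size scaling, 66.1% at a 4-fold induction, 66.9% when genes were chosen at the same time, and 54% to 61.7% without each library. At 24 h it moved from 69.5% to 65.1%, 74.4%, 76.1% (4-fold) and 75.7% (same time), and 63.1% to 72% without each library. The cause was not tested. With fry, amino acid transporters in TNF against untreated cells at 8 h (adjusted p = 0.0491) and autophagy and lysosome genes for HF before TNF at 8 h (0.00985) were called in the direction opposite to that of camera, which had not called them. In the same direction as camera, fry called 62 list results that camera had not called. Under the estimated correlation 43 camera calls were lost.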

Other observations

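The remaining lists are given here, with further values for some lists named above. NRF2 targets rose with HF alone (10 higher, 4 lower of 16 at 8 h, median 0.49, adjusted p = 0.00124, but adjusted p = 0.13 with an estimated correlation, and 10 and 3 at 24 h, 0.45, 0.00384, but adjusted p = 0.124). GCLC went from 37 to 221 and TXNRD1 from 493 to 1784 CPM at 8 h, and AKR1C1 fell from 217 to 32. Cell cycle genes did not pass with HF (3 higher, 15 lower of 28 at 8 h, adjusted p = 0.457, and 3 and 10 at 24 h, 0.671) or TNF (13 and 2, 0.819, and 15 and 2, 0.35). They fell with HF before TNF at 8 h (1 and 22, −0.83, 0.0193, but adjusted p = 0.43 with an estimated correlation), KIF20A by −2.09 and the replication clamp PCNA from 89.9 to 42.3 CPM. At 24 h that list did not pass (1 and 19, 0.0805), though MKI67 fell from 14.4 to 3.85 CPM. Targets of p53 did not pass with HF (4 higher and 8 lower at 8 h, adjusted p = 0.995, then 7 and 6, 0.442) or TNF (7 and 7, 0.525, then 7 and 8, 0.837). Nor did they with HF before TNF (4 and 5, 0.494, then 10 and 5, 0.224). The growth arrest gene GADD45A rose from 58.9 ± 0.772 to 311 ± 28.8 CPM with HF at 8 h and FAS from 59.8 to 291 with TNF. Autophagy and lysosome genes did not pass with HF (4 and 6, adjusted p = 0.98, then 4 and 6, 0.653), TNF (9 and 2, 0.826, then 5 and 3, 0.791) or HF before TNF (3 and 6, 0.955, then 3 and 8, 0.48). MAP1LC3B rose from 155 to 301 CPM with HF at 8 h. Ribosomal genes did not pass with HF alone (1 higher, 10 lower, 0.443, then 5 and 6, 0.888).

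Histone genes had 1 higher and 4 lower of 7 with HF at 8 h (adjusted p = 0.45), 3 and 1 at 24 h (0.328). They had 3 and 1 with TNF at 8 h (0.864) and 6 and 0 at 24 h (median 1.15, 0.0223, but adjusted p = 0.278 with an estimated correlation), where H2BC21 rose from 7.68 to 32.5 CPM. Counts were 0 and 5 (0.145) then 0 and 3 (0.68) with HF before TNF. Endothelial and mural markers had 0 higher and 6 lower of 9 with HF at 8 h (adjusted p = 0.0528) and 24 h (−1.19, 0.0312, but adjusted p = 0.109 with an estimated correlation). NOTCH3 fell from 122 to 29.5 CPM at 8 h and CDH5 at least 34.6-fold. They had 3 and 2 (0.864) then 3 and 3 (0.837) with TNF, which raised TEK from 58.4 to 218 CPM. With HF before TNF they had 1 and 5 (−1.30, 0.0236, but adjusted p = 0.0646 with an estimated correlation) then 0 and 6 (−1.71, 0.00652, 0.037). Chondrocyte and adipocyte markers did not pass with HF or TNF against untreated cells (1 higher, 3 lower of 7, 0.445, then 0 and 4, 0.141 with HF, and 2 and 2, 0.942, then 1 and 3, 0.35 with TNF). With HF before TNF they had 0 and 3 (0.21), then 0 and 5 (0.354). From 8 h to 24 h of TNF they had 0 and 4 (0.0459, but adjusted p = 0.209 with an estimated correlation). With HF at 8 h 2 of 4 macrophage markers fell, CD14 from 4.6 to 1.52 CPM, and 3 of 3 lymphocyte markers, JCHAIN from 16.2 ± 0.606 to 7.22 ± 0.475, too few for a list test. Counts adjusted over the list alone differed for ribosomal genes with HF (0 and 10, then 3 and 6), cell cycle genes with HF before TNF at 8 h (23 lower), and endothelial (4 and 3) and chondrocyte markers (4 lower) with TNF at 24 h. HF before TNF at 24 h then had 7 lower endothelial markers.

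The regulators here were chosen after their values were seen, and of them the naming rule reached only IRF1, in other comparisons. MYC stood at 21.6 CPM in untreated cells, 176 with HF and 44.9 with TNF at 8 h and 203 with both (log2 fold change of HF before TNF 2.18 at 8 h and 2.46 at 24 h). IRF1 went from 692 CPM with TNF at 8 h to 253 with both, TLR3 from 159 to 32.4, JAK2 from 259 to 126, and IFNAR2 from 76.8 to 38.5. RIGI, whose product senses RNA, went from 1370 to 361. IFNB1 lay under the filter, with 9 counts in each of the TNF groups with and without HF at 8 h and 21 and 6 at 24 h without and with HF.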
